A study of Mus musculus with 3 samples.

How the data were processed

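RNA from 3 striated muscles of male C57BL/6 mice aged 8 weeks was analysed: the apex of the heart, the whole extensor digitorum longus (EDL) and the whole soleus. Each tissue had 1 library. Per the labels' protocols, RNA was extracted with mirVana reagents, cDNA was made with a SMARTer kit and barcoded primers, molecules of 5 to 10 kb were selected on a BluePippin instrument, and libraries were sequenced by the PacBio Iso-Seq method. Iso-Seq reads a cDNA from end to end. A full-length read comes from a single sequenced molecule, and a consensus read, also called a cluster read, merges full-length reads judged to come from the same transcript. How many mice went into a library is not given in the sources used here.

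Per the authors' deposited protocol, consensus reads were aligned to the mouse build mm10 (GRCm38) and counted per gene name with htseq-count. The submitters' processing notes name STAR 2.5.0am as a tool and mm10 and GRCm38 as builds. The authors deposited gene values as raw counts of consensus reads, without scaling. Per the same protocol, the authors kept genes with at least 10 consensus reads in some library and dropped names ending in Rik, which left 686 genes. They divided the exons of these genes, from annotation release 85, into exonic parts with the annotation script of DEXSeq, and the tool exCOVator gave deposited counts of consensus and of full-length reads that cover each part and that hold it. The deposited fraction for each part is the number of reads holding it over the number covering it, and the 2 counts were used here to recompute it as a percent. Parts with a u in their number were found in the reads and are absent from that annotation. The authors kept parts covered by at least 30 consensus reads in some library and differing by at least 20 percentage points, and then checked the parts by eye in a genome viewer. The other deposited values used are the authors' list memberships, exon numbers and positions. In the authors' deposited table of filter steps, 5053 exons of 143 genes passed the coverage step, 327 of 55 genes passed the difference step, and 285 of 51 genes were kept after the check by eye. That table words the coverage step in full-length reads. Recomputed here, 30 consensus reads gave the same 5053 parts in 143 genes, while 30 full-length reads gave 15356 parts in 483 genes, so the rule was taken as consensus reads. For Nrap, Neb and Ttn, the authors' tool exPhaser gave deposited counts of full-length reads for each combination of exons on reads that span a whole region. The deposited exon positions of these regions were counted from 0 and are printed here counted from 1.

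The libraries held 20286 consensus reads in cardiac muscle, 21767 in EDL and 19110 in soleus, built from 96946, 101804 and 117237 full-length reads. Of the consensus reads, 9.78%, 8.92% and 8.64% were assigned to no single gene and stayed out of all totals. Reads in no annotated gene were 5.12%, 3.95% and 3.14%. The totals used for scaling were 18302, 19826 and 17459 reads in genes, so 1 read stood for 54.6, 50.4 and 57.3 RPM, the reads of a gene scaled to a common library total.

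Groups were taken from the tissue label. With 1 library per tissue, no replicate check was possible and no p-value across genes was computed. Gene abundance was compared in each of the 3 pairs of tissues as the ratio of RPM from consensus reads, with an exact conditional binomial 95% interval. A gene was called higher in a library when the pair held at least 20 of its reads and the interval lay wholly beyond 2-fold. Where a count was 0, the ratio was taken against a floor of 3 counts in that library and is given as at least that size. The lower end of the exact 95% interval lies below it. Each fixed gene list was described by the median of its members' log2 ratios, with 0.5 added to each count, over members with at least 20 reads in the 3 libraries together. The median was set against those of 10000 random lists of the same size matched on mean abundance, drawn from the 25 genes on each side in rank. Medians were given only for lists with at least 3 such members.

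Exon use was compared with a two-sided Fisher's exact test on full-length reads that held or lacked a part, with Benjamini-Hochberg adjustment over all parts tested in the pair. The rule fixed in advance gave way, as it stated, to the coverage and difference rule of the deposited protocol: a part was called when it had 30 consensus reads in some library, a difference of at least 20 points and an adjusted p under 0.05. Phased structures were given as shares of all full-length reads phased over the region, with exact Clopper-Pearson 95% intervals. A structure with at least 5% in some library was tested with Fisher's exact test in pairs of libraries, with Benjamini-Hochberg adjustment over all structures and pairs. These tests compare libraries, not tissues in general. Full-length reads that share a consensus read also share its exon calls and are not independent, so the tests and intervals on full-length reads cover counting error only and overstate the precision.

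Genes, lists, rules for naming genes and the first set of other settings were chosen before the data were examined. The text names, for each pair and direction, up to 10 genes with the largest lower bound of the ratio, 2 to 4 members of each fixed list by read number, and up to 10 called parts per pair outside Ttn, Neb and Nrap, 1 per gene, by size of difference. It also names the 10 parts of each of those 3 genes with the largest difference, the parts of the phased regions, called members of the splicing lists, the authors' newly found parts and the structures with at least 5%. The first set held 2 other scalings, other read and coverage minimums, other fold and percentage point thresholds, no test, leaving out Ttn, Neb and Nrap, 1 part per gene, the authors' checked tables, and other sets of structures. Added after seeing the data were 30 consensus reads in both libraries, tests on consensus reads, leaving out the authors' artifact parts, counting adjoining parts once, gene ratios from full-length reads over the exonic part of the gene with most reads in the pair, and shares among kept structures.

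Each step was tested on simulated data drawn from the real libraries, with 200 genes or parts changed. Of genes changed 4-fold, 74% were recovered between EDL and soleus, 78% between cardiac muscle and EDL and 68% between cardiac muscle and soleus. All genes changed 8-fold were recovered, and 0 unchanged genes were called. Of parts changed by 40 points, 86% were recovered between EDL and soleus, 73% between cardiac muscle and EDL and 82% between cardiac muscle and soleus, with 0 wrong calls. Simulated reads were independent, without reads that share a consensus read and without spread between libraries of a tissue. The 0 wrong calls of genes and parts therefore say nothing of errors from these sources. Of 1000 unchanged lists between EDL and soleus, 5.9% fell outside the random range. Exon annotation for the text came from GENCODE release M21 on GRCm38. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and Biopython 1.88 were used. Results of some genes that meet these rules are not reported here.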

Results

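Iso-Seq, which reads cDNA molecules from end to end, was applied to 3 striated muscles of male C57BL/6 mice at 8 weeks of age. They were the apex of the heart, the whole extensor digitorum longus (EDL), a fast-twitch muscle of the lower leg, and the whole soleus, a slow-twitch calf muscle. The cDNA had been size-selected at 5 to 10 kb, so the libraries were made of long cDNA molecules. Those of Ttn and Neb covered parts of these genes. In EDL, no single exonic part was covered by more than 342 of 1264 Ttn and 259 of 451 Neb consensus reads. Each tissue had 1 library, so no difference between tissues has a replicate check, and no p-value across genes is given. The cardiac library held 18302 consensus reads in 2260 genes, the EDL library 19826 in 2320 genes and the soleus library 17459 in 2097 genes. A consensus read merged on average 4.78 full-length reads in cardiac muscle, 4.68 in EDL and 6.13 in soleus. Genes with a read were long: the median longest transcript was 5435 nt for genes with a read and 1141 nt for genes without. Genes of shorter transcripts can therefore be missing or undercounted whatever their abundance, and a ratio or list median that rests on them is uncertain. All coordinates are on GRCm38 (mm10). Intervals are at 95% and cover counting error only, and a test on reads compares libraries, not tissues in general. Gene intervals count each consensus read as 1 molecule, although it can merge several full-length reads, so they leave out the effect of this merging. Where a library had 0 reads of a gene, the ratio was taken against a floor of 3 counts and is given as at least that size. A share of 0 among full-length reads is given with the limit that 3 counts would set. Exact 95% intervals reach further than both limits. For Dsp in cardiac muscle over EDL the lower end is 34.4-fold, against 43.0-fold by the floor. For 0 of 555 cardiac Nrap reads the upper end is 0.662%, against 0.541%.

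EDL and soleus differed in myosin heavy chains, the motor proteins that set fibre type. Myh7, the slow and cardiac beta heavy chain, had 433 consensus reads in soleus and 18 in EDL, 27.3-fold higher in soleus (interval 17.1 to 46.5). Myh2, the fast IIa chain, was 3.53-fold higher in soleus (2.60 to 4.86), with 174 reads against 56. Myh4, the fast IIb chain, was 2.82-fold higher in EDL (2.32 to 3.44), with 432 reads against 135. Phka1, the muscle alpha subunit of phosphorylase kinase, which drives glycogen breakdown, was 2.89-fold higher in EDL (2.07 to 4.11). Myh1, the fast IIx chain, had 119 reads in EDL and 100 in soleus and passed in neither direction.

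Atp2a2, Ablim1, Inpp4b and Cyfip2 were also higher in soleus than in EDL. Atp2a2, the calcium pump of slow and cardiac muscle, had 21 reads in soleus and 0 in EDL, at least 7.95-fold higher. It had only 13 reads in cardiac muscle. Ablim1, an actin-binding protein, was 8.56-fold higher in soleus (4.78 to 16.6). Inpp4b, a lipid phosphatase, was 7.57-fold higher (2.25 to 39.8), and Cyfip2, a regulator of actin assembly, 21.6-fold (3.43 to 896) on 19 reads against 1. Of 494 genes with at least 20 reads in the pair, 2 were higher in EDL, 7 in soleus and 485 in neither. With median-of-ratios scaling the numbers were 4 in EDL and 7 in soleus. Counted by full-length reads over each gene's best covered part, the ratio was 453-fold for Myh7, 64.5-fold for Ablim1, 23.2-fold for Myh2, 7.10-fold for Myh4 and 7.15-fold for Phka1. Myh1, not called by consensus reads, was 2.03-fold higher in soleus by this count.

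Lists of fibre-type and glycogen genes were compared between EDL and soleus. Of the 17 fast-twitch genes, 6 were measured: Myh4 and Phka1 were higher in EDL, Myh2 in soleus and 3 in neither, among them Tnnt3 with 32 reads against 18 and Myl1 with 25 against 10. Their median log2 ratio of EDL over soleus was 0.86, at the 99.8 percentile of random lists. Of the 12 slow-twitch genes, 3 were measured: Myh7 and Atp2a2 were higher in soleus and Mybpc1, with 18 reads in EDL and 11 in soleus, in neither. Their median was -4.73, and -2.99 with genes at 0 set to their bound. Of the 15 genes of glycogen use and glycolysis, 3 were measured: Phka1 was higher in EDL and 2 passed in neither direction, among them Hk2, with 55 reads against 53. Their median was 1.04, at the 98.4 percentile.

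In the following lists no gene passed the 2-fold bar between EDL and soleus, though some intervals lay wholly on 1 side of equal abundance. In skeletal excitation-contraction coupling, 5 of 12 genes were measured, and Cacna1s, the voltage sensor, had 129 reads in EDL and 87 in soleus and Ryr1, the calcium release channel, 100 and 35, 2.52-fold more in EDL (1.70 to 3.81). Among giant and large sarcomere proteins, 14 genes had enough reads in the pair; Ttn had 1264 and 527 reads, 2.11-fold more in EDL (1.91 to 2.34), Neb 451 and 249, 1.60-fold (1.36 to 1.87), and Cmya5 179 and 132, while Nrap had 1.94-fold more in soleus (1.42 to 2.65). Other intervals of this list off 1 were those of Xirp2 and Myom2, toward EDL, and of Flnc, Xirp1, Myom3 and Actn2, toward soleus. By full-length reads over the best covered part, EDL over soleus was only 0.91 for Ttn and 1.08 for Neb. Reads of Ttn and Neb covered parts of these genes, so their number is not a count of whole transcripts. Soleus over EDL was 2.64 for Nrap by this count. Of 13 dystrophin complex and costamere genes, Plec had 82 and 88 reads, Dst 80 and 77 and Dag1 26 and 46, 2.01-fold more in soleus (1.22 to 3.39). The 3 measured splicing regulators were Mbnl1 with 58 and 29 reads, 1.76-fold more in EDL (1.11 to 2.85), Rbm20 with 19 and 18 and Rbfox2 with 21 and 30. Of 18 mitochondrial and fatty acid oxidation genes, 2 were measured, Acacb with 43 and 52 reads and Ogdh with 15 and 19.

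Few markers of other cell types had enough reads, so how alike the 2 leg muscles are in cell content was not settled. The fibroblast and matrix list had 8 measured genes of 17, and Col4a1 had 39 reads in EDL and 35 in soleus and Col4a2 22 and 18. The endothelial list had 4 of 11, with Kdr at 17 and 22 and Ptprb at 24 and 17. Smooth muscle and pericyte genes had 2 of 8, with Myh11 at 14 and 14 and Pdgfrb at 12 and 8. Blood and immune genes had 2 of 9, with Lrp1 at 9 and 9 and Mrc1 at 7 and 6. No adipocyte or nerve marker was measured out of 8 in each list. None of these markers was called in any pair of tissues. Against the heart some intervals still lay off 1: Col4a1 had 1.97-fold more in cardiac muscle than in EDL (1.32 to 2.99) and 1.94-fold more than in soleus (1.27 to 2.99), Col4a2 1.87-fold (1.08 to 3.32) and 2.01-fold (1.12 to 3.75), and Kdr 2.29-fold more than in EDL (1.26 to 4.36). Fn1 lay the other way, with 1, 9 and 14 reads in cardiac muscle, EDL and soleus, too few in each pair for a call.

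Myh6, Dsp, Ryr2, Chrm2 and Nebl were higher in the heart than in both leg muscles. Myh6, the fast cardiac alpha heavy chain, had 2060 reads in cardiac muscle, 30 in EDL and 31 in soleus, 74.4-fold higher than in EDL (51.9 to 110.5) and 63.4-fold higher than in soleus (44.5 to 93.5). Dsp, the desmoplakin of cell junctions, had 119 reads in cardiac muscle and 0 in each leg muscle, at least 43.0-fold higher than in EDL and at least 37.8-fold higher than in soleus. Ryr2, the cardiac calcium release channel, had 94 reads in cardiac muscle and 0 in each leg muscle, at least 33.9-fold and 29.9-fold higher. Chrm2, the muscarinic receptor of the vagal response, had 56 reads and was at least 20.2-fold and 17.8-fold higher, with 0 reads in either leg muscle. Nebl, the small relative of nebulin at the cardiac Z-disc, had 51 reads against 2 in EDL, 27.6-fold (7.27 to 234), and 0 in soleus, at least 16.2-fold.

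Other genes higher in the heart were also counted at 0 in both leg muscles. Pde1c, a cyclic nucleotide phosphodiesterase, and Gm10435, with 22 reads each, were at least 7.94-fold higher than in EDL and 7.0-fold higher than in soleus. Dsg2, a desmosomal cadherin, and Tbx20, a cardiac transcription factor, with 20 reads each, were at least 7.22-fold and 6.36-fold higher. Of 20 cardiomyocyte genes, 8 were measured, and 5 were higher in cardiac muscle than in either leg muscle, among them Myh6, Ryr2, Nebl and Slc8a1, the sodium-calcium exchanger. Myh7, also on this list, had 38 cardiac reads against 433 in soleus and 18 in EDL, higher in soleus and in neither against EDL. Fhod3 had 47, 19 and 14 reads in cardiac muscle, EDL and soleus and Rbm20 had 43, 19 and 18, and neither passed. The list's median log2 ratio was 3.37 over EDL and 4.48 over soleus, and 2.75 and 3.27 with genes at 0 set to their bound.

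The leg muscles were higher than the heart in nebulin, in fast myosins and in the skeletal calcium release machinery. Neb, the ruler of the skeletal thin filament, had 2 reads in cardiac muscle, 451 in EDL and 249 in soleus, 208-fold higher in EDL (57.3 to 1724) and 131-fold higher in soleus (35.8 to 1084). Cacna1s had 2 cardiac reads and was 59.5-fold higher in EDL (16.2 to 497) and 45.6-fold higher in soleus (12.3 to 382). Ryr1 had 0 cardiac reads and was at least 30.8-fold higher in EDL and 12.2-fold higher in soleus. Myh4 was 23.5-fold higher in EDL (14.5 to 40.6) and 8.32-fold higher in soleus (5.01 to 14.7), on 17 cardiac reads. Myh1 was 27.5-fold higher in EDL (10.4 to 102) and 26.2-fold higher in soleus (9.92 to 98.1).

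Further genes were higher in EDL or soleus than in the heart, and some in both. In EDL, Tnnt3, fast troponin T, had 32 reads, Agbl1, a cytosolic carboxypeptidase, 28, and Myl1, a fast myosin light chain, 25. All had 0 cardiac reads and were at least 9.85-fold, 8.62-fold and 7.69-fold higher. Whether these few reads came from whole transcripts within the selected size range was not checked. Ttll7, a tubulin-modifying enzyme, was 34.2-fold higher in EDL (5.76 to 1385) on 37 reads against 1, and Ano5, a membrane repair protein, 16.3-fold (5.29 to 81.6). In soleus, Myh2 was 36.5-fold higher than in cardiac muscle (15.3 to 114), Myh7 11.9-fold (8.56 to 17.1) and 3425401B19Rik 14.1-fold (6.57 to 36.0). Myom3, an M-band protein of the sarcomere, had 39 reads in soleus and 0 in cardiac muscle, at least 13.6-fold higher, and Agbl1 was at least 8.04-fold higher.

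All 6 measured fast-twitch genes were higher in EDL than in the heart, with a median log2 ratio of -4.56 for cardiac muscle over EDL. In soleus, 4 of them had enough reads in the pair, and Myh1, Myh2 and Myh4 were higher than in the heart while Phka1, with 31 cardiac and 46 soleus reads, was not called. Of the 5 measured excitation-contraction coupling genes, Cacna1s, Ryr1 and Scn4a, the skeletal sodium channel, were higher in each leg muscle than in the heart, and Srl and Cacna2d1 passed in neither pair. The median of this list was -3.25 for cardiac muscle over EDL and -2.95 over soleus. Among giant and large sarcomere genes, Nebl was higher in cardiac muscle, Neb and Xirp2 in EDL and Neb and Myom3 in soleus, with 11 genes in neither direction in each pair; Ttn had 672 cardiac reads. In the costamere list 0 genes were called in any pair, and Sptbn1 had 108, 47 and 40 reads in cardiac muscle, EDL and soleus.

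In numbers, 500 genes had enough reads in cardiac muscle and EDL, and 16 were higher in cardiac muscle and 26 in EDL. For cardiac muscle and soleus, 473 genes had enough reads, and 16 were higher in cardiac muscle and 23 in soleus. Of the 10 fixed lists with 3 measured members, 3 lay outside the random range between EDL and soleus, 3 between cardiac muscle and EDL and 4 between cardiac muscle and soleus. Full-length reads gave larger ratios here too, 406-fold for Myh6 over EDL and 1323-fold for Myh2 in soleus over cardiac muscle. Scaling without the 10 most abundant genes of each library shifted every ratio between cardiac muscle and soleus by 0.10 on the log2 scale. With it, 17 genes were higher in cardiac muscle and 20 in soleus.

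**Figure D1:**
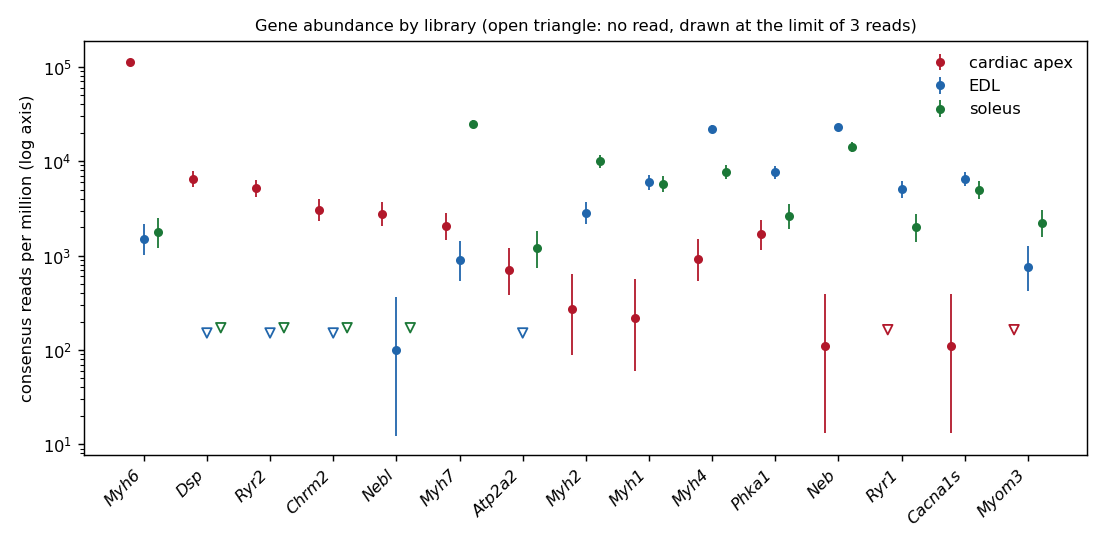
Abundance of selected genes in RPM, on a log axis, with 1 point per library and bars for the exact Poisson 95% interval. Myh6 reached 112556 RPM in cardiac muscle, Myh4 21790 RPM in EDL and Myh7 24801 RPM in soleus.

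Neb transcripts of EDL and soleus carried different exons at both of their variable sites. In EDL, 99.2% of full-length reads (98.3 to 99.7) held the alternative exon at 2:52185271-52185375 and 0.941% (0.407 to 1.85) held exon 123 at 2:52186012-52186116. In soleus, 65.0% (61.8 to 68.1) held the alternative exon and 34.8% (31.7 to 37.9) held exon 123. Both exons are coding and 105 nt long, and their sequences were identical at 58 of 114 aligned positions, 50.9%. The differences had adjusted p = 3.62e-91 for the alternative exon and 3.79e-89 for exon 123 (Fisher's exact test with Benjamini-Hochberg adjustment).

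The other Neb site lies toward the 3' end of the gene, which encodes the part of nebulin at the Z-disc, and there soleus held exons that EDL mostly lacked. Exon 147 (2:52157291-52157383) was held by 91.3% of soleus reads (89.2 to 93.1) and 6.67% of EDL reads (3.86 to 10.6), the widest gap of the gene. The coding exon at 2:52156355-52156447 stood at 87.8% and 6.67%, and the unannotated exon at 2:52154554-52154662, 109 nt, at 89.8% and 7.41%. The exon at 2:52153683-52153775, annotated in a non-coding transcript, stood at 89.0% and 8.98%. Exon 148 stood at 96.9% in soleus and 18.6% in EDL, exon 150 at 98.7% and 26%, exon 146 at 99.3% and 30%, exon 143 at 99.5% and 36.3%, exon 138 at 99.9% and 39.7%, and exon 151 at 99.5% and 41.5%. Exon 140 differed least, with 99.9% and 77.2%. In all, 14 Neb parts of 175 tested differed, 13 more used in soleus, and the same 14 passed when share and test were taken on consensus reads. Cardiac muscle had at most 1 Neb read over a part and gave no call.

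**Figure D2:**
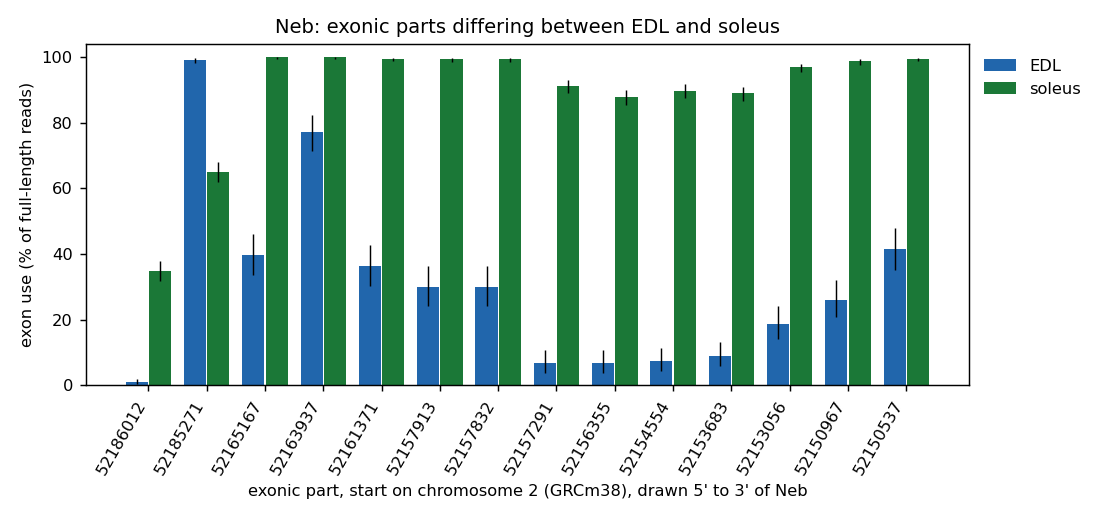
Percent of full-length reads that hold each Neb part differing between EDL and soleus, with exact 95% intervals, by start position on chromosome 2 from 5' to 3' of the gene. At 52185271 EDL reached 99.2% and soleus 65.0%, and at 52157291 EDL stood at 6.67% and soleus at 91.3%.

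Nrap, a nebulin-related anchoring protein at the ends of myofibrils, differed at exon 12. This 105 nt coding exon (19:56374364-56374468) was held by 0 of 567 cardiac reads, which allows a share of up to 0.529%, by 66.8% of EDL reads (63.6 to 70.0) and by 14.4% of soleus reads (13.1 to 15.8). EDL differed from cardiac muscle with adjusted p = 6.45e-178 and from soleus with adjusted p = 2.59e-179 (Fisher's exact test, Benjamini-Hochberg). By consensus reads the shares were 49.3% in EDL and 22.6% in soleus, and this pair no longer passed. Cardiac muscle and soleus differed by less than the 20 points required on full-length reads, but on consensus reads, with 0% and 22.6%, this pair passed. No other of the 53 Nrap parts tested differed in any pair.

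Titin transcripts of the heart left out a long coding stretch that both leg muscles held for the most part. Between exons 47 and 167 of Ttn (2:76821116-76903626), which encode the elastic part of the protein in the I-band, 123 parts had a median use of 0.760% in cardiac muscle, with a range of 0 to 12%. Their median use was 90.2% in EDL, with a range of 15.8 to 99.3%, and 91.7% in soleus, with a range of 0 to 98.8%. Of these parts, 119 differed between cardiac muscle and EDL and 105 between cardiac muscle and soleus, and 0 differed between EDL and soleus. Each part was left out by 249 to 261 cardiac reads, largely reads that skip the whole stretch. The calls are therefore not independent, though each enters the total counts as a separate part. Unannotated parts and parts without a single deposited exon number were left out here. The 123 parts hold none between 2:76828187 and 2:76840233, so exon use there is not described. Exon 50 (2:76900757-76901035) was held by 0 of 260 cardiac reads, which allows up to 1.15%, by 97.2% of EDL reads (93.6 to 99.1) and by 95.2% of soleus reads (76.2 to 99.9). The opposite held for a 2646 nt coding part that extends exon 45 (2:76907308-76909953), at 99.5% in cardiac muscle (97.4 to 100), 0 of 172 reads in EDL, which allows up to 1.74%, and 4.76% in soleus (0.120 to 23.8). Coverage was thin in the middle of this stretch: over exons 59 to 79, parts had 6 to 44 reads in EDL and 2 to 12 in soleus, against at least 260 in cardiac muscle. Soleus was thin elsewhere too, with 6 to 74 reads over exons 111 to 151 and 6 to 8 over exons 159 to 167, so that the lack of calls between EDL and soleus decides little where reads were this few.

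Ttn exons near the 5' end, which encode the part of titin at the Z-disc, differed between the tissues. Exon 11 (2:76965777-76965914) was held by 84.0% of cardiac reads (79.8 to 87.7), by 0 of 1257 EDL reads, which allows up to 0.239%, and by 0 of 208 soleus reads, which allows up to 1.44%. Exon 13 (2:76964475-76964612) stood at 71.4% in cardiac muscle (66.4 to 76.1), 1.67% in EDL (1.04 to 2.54) and 40.4% in soleus (33.7 to 47.4). Exon 12, whose larger part lies at 2:76965096-76965228, stood at 9.24% (6.45 to 12.7), 2.07% (1.36 to 3.02) and 41.3% (34.6 to 48.4). A 6520 nt coding exon at 2:76913944-76920463, the end of a short titin form, stood at 19.7% (14.8 to 25.4), 50.1% (44.7 to 55.5) and 82.5% (74.5 to 88.8).

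Near the 3' end of Ttn, exon 312 (2:76705670-76705972, 303 nt) was held by 100% of cardiac reads (99.0 to 100), 75.0% of EDL reads (72.2 to 77.7) and 98.8% of soleus reads (98.2 to 99.2). Exon 191 (2:76802231-76802497, 267 nt) was held by 36.2% of cardiac reads (30 to 42.8), 98.9% of EDL reads (97.2 to 99.7) and 97.1% of soleus reads (85.1 to 99.9). In all, 387 Ttn parts were tested in each pair; 5 differed between EDL and soleus, 151 between cardiac muscle and EDL and 138 between cardiac muscle and soleus. On consensus reads, 124 and 110 of the calls against the heart passed again, but between EDL and soleus only exon 312 did, so exons 12 and 13 and the 6520 nt exon rest there on full-length reads. So do exon 13 between cardiac muscle and soleus and the 6520 nt exon between cardiac muscle and EDL. In cardiac muscle, EDL and soleus the consensus shares were 55.3%, 12.3% and 39.3% for exon 13, 28.4%, 44.8% and 70.6% for the 6520 nt exon and 8.51%, 15.1% and 42.9% for exon 12, where cardiac muscle lay under EDL, the reverse of the full-length shares.

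**Figure D3:**
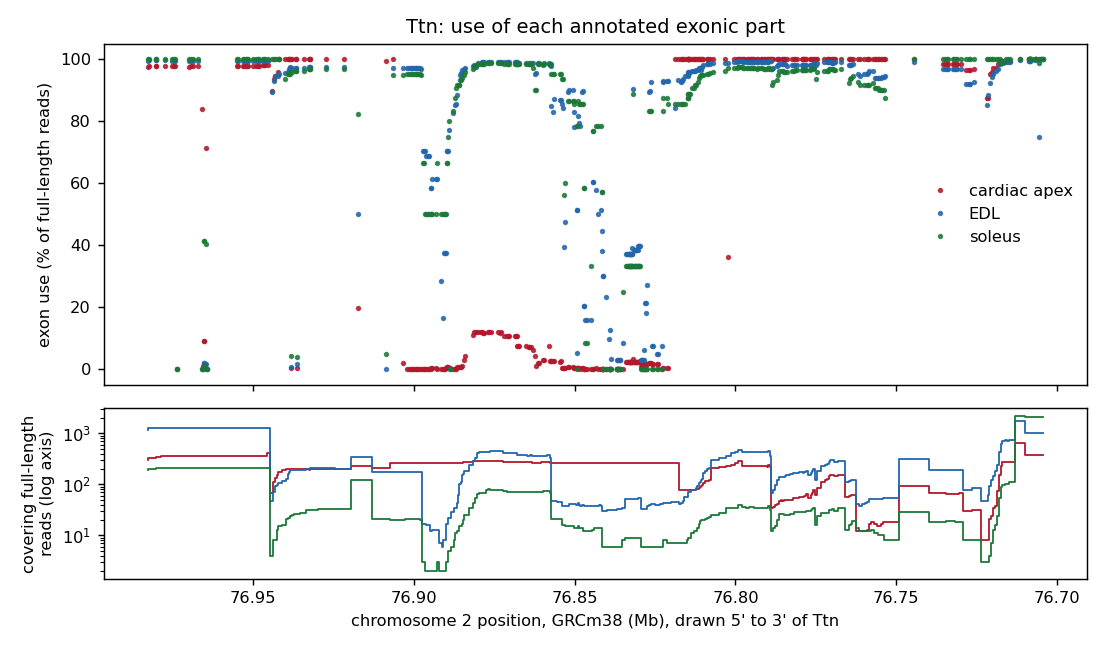
Percent of full-length reads that hold each annotated Ttn part in the 3 libraries (upper panel) and the reads that cover it, on a log axis (lower panel), by position on chromosome 2 from 5' to 3' of the gene. Over the 123 numbered parts of exons 47 to 167 cardiac muscle stayed at or under 12%, while the medians of EDL and soleus were 90.2% and 91.7%.

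Reads that span several exons gave the combinations themselves. Over the whole of Nrap, the structure without exon 12 made up 97.5% of 555 cardiac reads (95.8 to 98.6), 33.5% of 837 EDL reads (30.3 to 36.8) and 85.6% of 2544 soleus reads (84.1 to 86.9). The structure with all its exons made up 66.5% in EDL (63.2 to 69.7), 13.2% in soleus (11.9 to 14.5) and 0 in cardiac muscle, which allows up to 0.541%.

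Over the phased region of Neb, which spans both variable sites, the 856 soleus reads fell mainly into 2 structures. The form with the alternative exon and all the 3' exons made up 50.8% in soleus and 5.88% in EDL, and the form with exon 123 and all the 3' exons 34.8% in soleus and 0 of 238 reads in EDL, which allows up to 1.26%. In EDL, a form lacking exon 123 and 10 of the 3' exons made up 29.8% and a form lacking exon 140 as well 17.6%, and neither was seen in soleus, where 0 of 856 allows up to 0.350%. A form lacking exon 123 and a run of 4 exons at and after exon 147 made up 8.40% in EDL and 4.67% in soleus. The EDL reads were spread over 37 structures; counted among the structures the authors kept, the 3 EDL shares became 45.8%, 27.1% and 12.9%.

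Over Ttn exons 10 to 14, the heart and the leg muscles had different leading structures, and soleus held another that was rare in EDL. The form without exon 12 made up 61.1% of 357 cardiac reads and was found in 0 of 1257 EDL reads, which allows up to 0.239%, and 0 of 208 soleus reads, which allows up to 1.44%. The form without exons 11, 12 and 13 made up 97.5% in EDL, 58.7% in soleus and 10.1% in cardiac muscle. The form without exon 11 made up 40.4% in soleus, 1.67% in EDL and 2.80% in cardiac muscle. Cardiac muscle also held 16.5% without exons 12 and 13 and 6.44% with all of them. From exon 44, reads ran into the 6520 nt exon in 3.61% of cardiac, 13.6% of EDL and 34.4% of 32 soleus reads. These shares lie far under the 19.7%, 50.1% and 82.5% of all reads that cover this exon, and which of the 2 measures the short titin form was not tested.

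Over Ttn exons 45 to 50, the form with the extended exon 45 and without exons 47 to 50 made up 97.6% of 207 cardiac reads and was found in 0 of 165 EDL reads, which allows up to 1.82%, and 0 of 20 soleus reads, which allows up to 15%. The form with exons 47 to 50 and without the extension made up 97.0% in EDL and 95% in soleus. Of the cardiac reads that run from exon 45 past exon 167, 99.0% (96.3 to 99.9) joined the extended exon 45 to the exons after 167, and the 1 read of each leg muscle that spanned it lacked every exon of the region. The structure that lacked exon 191 alone made up 67.7% of 198 cardiac reads, 0 of 285 EDL reads, which allows up to 1.05%, and 0 of 22 soleus reads, which allows up to 13.6%; another 3 EDL reads and 1 soleus read lacked every variable exon of this region. Exon 312 was left out of 25% in EDL, 1.21% in soleus and 0 of 375 reads in cardiac muscle, which allows up to 0.8%. Fisher's exact test with Benjamini-Hochberg adjustment was run 53 times on 21 structures, and 44 tests passed, with adjusted p up to 0.0423 and, at the smallest, 1.75e-253 for the form without exons 11, 12 and 13 between cardiac muscle and EDL. Of these, 2 set the cardiac reads that run past exon 167 against the 1 read of a leg muscle and decide nothing.

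**Figure D4:**
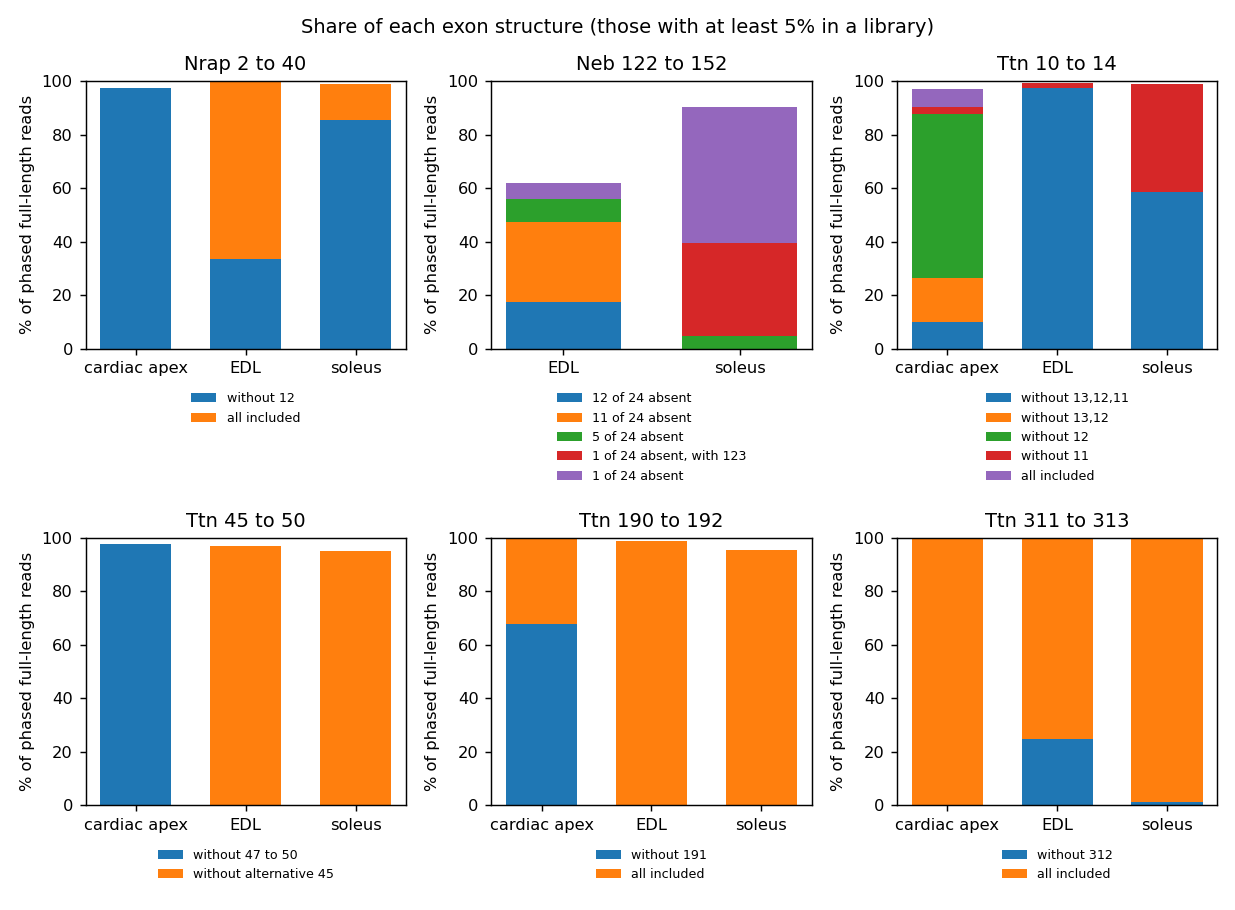
Percent of the full-length reads spanning each region that carry each exon structure with at least 5% in some library, as stacked bars for the 3 libraries (EDL and soleus for Neb). The Nrap structure without exon 12 reached 97.5% in cardiac muscle, 33.5% in EDL and 85.6% in soleus.

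Outside these 3 genes, EDL and soleus differed in a channel subunit and a glycogen enzyme on both kinds of read. Abcc9, a regulatory subunit of ATP-sensitive potassium channels, held its 39 nt coding exon at 6:142648027-142648065 in 31.9% of EDL reads (21.4 to 44), 98.0% of soleus reads (93.0 to 99.8) and 100% of cardiac reads (88.4 to 100). Phka1 held a 177 nt coding exon at X:102557096-102557272 in 56.5% of EDL reads (54.4 to 58.6), 5.13% of soleus reads (3.07 to 7.98) and 15% of cardiac reads (8.65 to 23.5). The differences between EDL and soleus had adjusted p = 1.63e-20 and 1.09e-81 (Fisher's exact test, Benjamini-Hochberg).

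The other named parts of this pair passed on full-length reads only, and the gap was much smaller on consensus reads for some. Spag9, a scaffold of kinase signalling, used a 39 nt exon in 45% of EDL and 86.0% of soleus reads. Kif1b, a kinesin motor, used a 42 nt exon in 84.2% and 52.3%, and Mast2, a kinase, a 21 nt exon at 4:116333413-116333433 in 73.2% and 29.4%. Sox6, a transcription factor of fibre type, used a 3 nt part in 53.9% and 9.68%, Ablim1 an 84 nt exon in 53.8% of 13 EDL reads and 95.9% of soleus reads, and Ankrd28 a 1859 nt part, a coding exon in a later annotation than the authors', in 51.6% and 91.2%. By consensus reads Sox6 stood at 33.3% and 23.8%, Mast2 at 51.5% and 37.0% and Kif1b at 70.6% and 58.0%. Amotl1 used a 267 nt part in 51.9% and 1.86%. Ryr1 had 6 parts at 100% in EDL and 60% to 66.7% in soleus, where they rested on 5 or 6 reads, and a 35 nt Myh2 part, at 84.3% and 24.4%, is also in the authors' list of artifacts. Outside Ttn, Neb and Nrap 37 parts in 22 genes differed between EDL and soleus, 27 more used in EDL, and 2 of them passed again on consensus reads.

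Exons of Lmo7, Limch1, Svil and Map4 set the heart apart from both leg muscles. Lmo7, a junction and actin-binding protein, held an unannotated 42 nt exon at 14:101915893-101915934 in 85% of cardiac reads (79.7 to 89.4), 6.58% of EDL reads (2.17 to 14.7) and 0 of 160 soleus reads, which allows up to 1.88%. Another unannotated Lmo7 part, of 204 nt, went the other way, with 16.9%, 78.9% and 74.4%. Limch1, a relative of Lmo7, held an unannotated 271 nt part at 5:66975549-66975819 in 0 of 82 cardiac reads, which allows up to 3.66%, 88.0% of EDL reads (75.7 to 95.5) and 81.9% of soleus reads (72.0 to 89.5). Svil, the supervillin of costameres, held a 165 nt coding exon at 18:5057275-5057439 in 57.3% of cardiac reads (47.2 to 67.0), 99.2% of EDL reads (95.6 to 100) and 93.8% of soleus reads (88.5 to 97.1). Map4, a microtubule-binding protein, held a 3180 nt coding exon at 9:110037288-110040467 in 36.7% of 30 cardiac reads (19.9 to 56.1), 89.8% of EDL reads (79.2 to 96.2) and 92.9% of soleus reads (86.0 to 97.1).

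Exons of other genes differed from the heart in 1 or both of these pairs. Mast2 used its 21 nt exon in 0 of 132 cardiac reads, which allows up to 2.27%, and Clasp1, a microtubule protein, a 54 nt exon in 97.1% of cardiac reads, 11.1% of 9 EDL reads and 60% of 15 soleus reads. Clip1, a microtubule plus-end protein, used a 195 nt part in 32.0% of cardiac reads and 0 of 141 EDL reads, which allows up to 2.13%. Ankrd28 used its 1859 nt part in 14.3% of 21 cardiac reads, against 91.2% in soleus. Among the calls lost on consensus reads were some of Mef2c and Lmo7, others of Clip1, Gpam and Myh6, that of Clasp1 against soleus, and those of Nebl, with 2 EDL reads, of Ppip5k2, with 8, and of Synm, with 5 cardiac reads. Consensus reads are fewer, and some of these differences stayed nearly as large, such as 95.7 points for Nebl and 66.7 for a Mef2c part. Parts of Amotl1, Gpam, Ppp1r12b, Mef2c and Myh6 among the widest gaps are in the authors' artifact list. Between cardiac muscle and EDL 88 parts in 31 genes differed outside Ttn, Neb and Nrap, 55 more used in cardiac muscle, and 35 passed again on consensus reads. Between cardiac muscle and soleus 72 parts in 31 genes differed, 39 more used in cardiac muscle, and 36 passed again.

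**Figure D5:**
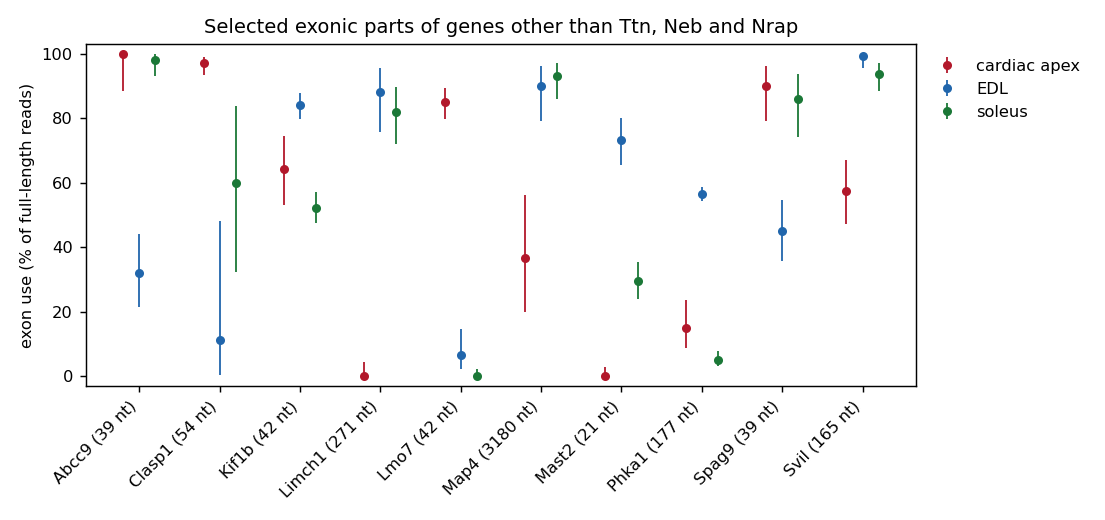
Percent of full-length reads that hold selected parts of genes other than Ttn, Neb and Nrap, with exact 95% intervals, in the 3 libraries. Abcc9 stood at 31.9% in EDL against 98.0% in soleus, and Lmo7 at 85% in cardiac muscle against 6.58% in EDL.

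In total, 57 of 4935 parts in 25 genes differed between EDL and soleus, 240 of 4762 in 33 genes between cardiac muscle and EDL and 210 of 4736 in 32 genes between cardiac muscle and soleus by Fisher's exact test with Benjamini-Hochberg adjustment and a difference of at least 20 points. On consensus reads, 17, 160 and 146 of these passed again. With 30 consensus reads required in both libraries of a pair, the counts were 31, 146 and 52.

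Genes described as targets of RBM20, a splicing regulator of the heart, gave 5 differing parts between EDL and soleus, 174 between cardiac muscle and EDL and 159 between cardiac muscle and soleus; adjusted over the list alone, these counts grew by 0, 3 and 10. Ttn alone gave 5, 151 and 138 of them, and most of the Mef2c parts among the rest are in the authors' artifact list. Of its 19 genes, 7 had covered parts; Ttn, Lmo7 and Mef2c had differing parts, while Dst, Fhod3 and Myom1, with tested parts in all pairs, had none. Genes with described muscle-regulated exons gave 27, 189 and 162 parts; adjusted over the list alone, 27, 193 and 172. Of its 45 genes, 20 had covered parts and 11 differed in some pair, among them Ttn, Neb, Nrap, Svil, Lmo7, Mef2c, Clip1, Kif1b, Ryr1 and Nebl. Mef2c, a transcription factor of muscle, rested on few cardiac reads: its 66 nt exon at 13:83625470-83625535 was held by 0 of 12 cardiac reads, which allows up to 25%, by 50.5% of EDL and 65.3% of soleus reads. The call against EDL was lost on consensus reads, where the gap was 47.1 points. Flnc, with 33 parts tested in each pair, and Mbnl1, with 45, had no part past the threshold.

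The authors marked 14 parts in 8 genes as newly found, and 11 of them differed here in some pair. Besides those of Neb, Lmo7 and Limch1, Cltc, the clathrin heavy chain, held a 43 nt part at 11:86696176-86696218 in 2.27% of cardiac reads (0.916 to 4.61), 63.8% of EDL reads (58.2 to 69.2) and 52.7% of soleus reads (46.2 to 59.2). Ubr3, a ubiquitin ligase, held a 33 nt part at 2:69971402-69971434 in 52.8% (38.6 to 66.7), 98.0% (93.0 to 99.8) and 100% (93.3 to 100). Zcchc6, an RNA-tailing enzyme, held a 65 nt part at 13:59779137-59779201 in 2.63% (0.0666 to 13.8), 42.9% (26.3 to 60.6) and 28.9% (19.5 to 39.9). By consensus reads this part stood at 5% in cardiac muscle, 31.8% in EDL and 35.3% in soleus. Its calls were lost there, though both leg muscles stayed above the heart. Myom2, an M-band protein, held a 319 nt part in 11% of cardiac and 32.7% of soleus reads, a call lost on consensus reads. A Phldb1 part, with 21.5%, 34.3% and 42.1%, passed in no pair, and by consensus reads EDL, with 33.3%, lay above soleus, with 28.6%. Of the authors' 285 curated parts, 260 also differed here, with 155 of 158 in Ttn, 14 of 14 in Neb, 1 of 1 in Nrap and 90 of 112 in 48 other genes. Of 42 parts the authors listed as artifacts, 31 in 13 genes passed the test here.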

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

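The values of this part were looked at after the counts had been seen, and no explanation of them was tested.

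Part of each library lay outside the gene annotation used for counting. Of the consensus reads, 5.12% in cardiac muscle, 3.95% in EDL and 3.14% in soleus fell in no annotated gene. These were 1039, 859 and 601 reads, well above the limit of 3 reads that a count of 0 allows. They enter no comparison of the report. Where they lie on the genome was not analysed here.

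Some unannotated exonic parts were used alike in the libraries and gave no comparison. Of 191 covered parts without an annotated exon, in 72 genes, 27 stand in a list of the authors. Another 12, in 9 genes, stood in no list and were held by at least 90% of full-length reads in every library that covered them. A difference between tissues is the reason for entry in those lists, so parts used alike in all libraries do not reach them. Of the 12, 5 lay wholly inside exons of a later annotation, in Fhod3, Gpam, Klhl24, Myh6 and Tsc2, and 2 partly, in Amotl1 and Gpam. The other 5 lay outside its exons. Scn4a, the skeletal sodium channel, held one of them (11:106317549-106318013) in 100% of reads of each library, with 5 cardiac reads (47.8 to 100), and Mast2 another (4:116371465-116371819) in 100% in cardiac muscle, 99.4% in EDL and 96.6% in soleus. Amotl1 (9:14662771-14663117), Gpam (19:55119766-55120084) and Myh4 (11:67237662-67237939) held the remaining ones. The Myh4 part lies before the annotated start of its gene and the Scn4a part past the annotated end. Whether a read can cover the Scn4a part without holding it was not checked.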

How the results depend on the processing

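The settings with consensus reads in exon tests, with 30 consensus reads in both libraries, with full-length reads for genes, with shares of the kept structures, without the artifact list and with adjoining parts merged were chosen after the data were seen; the others were planned. No called gene reversed its direction under any setting run. Of all 507 exon calls, 6 reversed on consensus reads, in AI314180, Gpam and Zfp106, none of them named above. With 1 library per tissue, leaving out a library was not an option, and where a cause is not named below, the cause was not tested.

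The number of genes called moved with the size of ratio required and the reads required. With the interval beyond 1-fold in place of 2-fold, 24 genes were higher in EDL and 36 in soleus, 46 in cardiac muscle and 66 in EDL, and 34 in cardiac muscle and 63 in soleus, as a lower bar allows. Beyond 4-fold the counts were 0 and 3 between EDL and soleus, 13 higher in EDL than in cardiac muscle and 12 higher in soleus than in cardiac muscle. With at least 50 reads, 3 were higher in soleus than in EDL, 7 in cardiac muscle and 13 in EDL, and 6 in cardiac muscle and 12 in soleus, since fewer genes were tested. With at least 10 reads, 27 were higher in cardiac muscle than in EDL and 35 in soleus than in cardiac muscle. Median-of-ratios scaling gave 4 genes higher in EDL than in soleus in place of 2.

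Between EDL and soleus, the 57 parts that differed in exon use became 35 at a coverage of 50 reads and 18 at 100. They became 31 with 30 consensus reads in both libraries, 20 with share and test on consensus reads and 17 with only the test on consensus reads. Without the test, 99 parts had the difference. Between cardiac muscle and EDL the 240 parts became 45 at a coverage of 100 and 146 with 30 consensus reads in both libraries, and between cardiac muscle and soleus the 210 became 41 and 52. Fewer parts were tested in these settings. Without Ttn, Neb and Nrap the counts were 37, 88 and 72, and with 1 part per gene 25, 33 and 32. Of the parts in those 3 genes, 41 were left between cardiac muscle and EDL at a coverage of 100; between cardiac muscle and soleus 39 were left at 100 and 38 with 30 consensus reads in both.

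For the 90 gene calls, 446 values kept their side of the threshold under planned settings and 47 did not, 40 of them beyond 4-fold, among them Myh4, Phka1, Cyfip2, Myh2 and Inpp4b between EDL and soleus and Xirp2 and Slc8a1 against the heart. The others were Alpk3, Kif5b and Inpp4b between cardiac muscle and soleus under both other scalings and Mef2c between cardiac muscle and EDL without the most abundant genes. Of the 446 kept values, 90 beyond 1-fold, 90 with at least 10 reads and 43 with at least 50 reads were fixed in advance. A lower bar keeps every call, and a read minimum changes no ratio or interval. The ratio by full-length reads lay within the interval by consensus reads in 15 values and outside in 21. Of the single parts named, 223 values kept their side and 17 did not under planned settings, and 129 and 52 under added ones. Counts of parts within a single gene stayed within 1.5 times in 50 values and left this range in 4 under planned settings, and 29 and 7 under added ones. List medians kept their side in 108 values and changed it in 6. The shares of phased structures stayed within their interval in 112 values under planned settings; counted among the kept structures, 47 did and 9 did not. Taking the share as reads holding a part over reads holding or lacking it gave the same values by construction. Depth set the limits: cardiac muscle had at most 1 read over a Neb part, and 2 to 12 soleus reads covered Ttn exons 59 to 79.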

Other observations

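All tests of this part were chosen after the results were seen.

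Some exon choices at different sites of a transcript stood together on the same full-length reads. The p-values take these reads as independent, though several can share a consensus read. In cardiac Ttn, 94.5% of the 255 reads with exon 13 also held exon 11, against 62.1% of the 95 reads without exon 13, leaving aside reads without any exon of the region (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.42e-12). For exon 12 the shares lay the other way there, with exon 11 in 69.7% of the 33 reads with exon 12 and 87.4% of the 317 without it, but only 4 consensus reads held exon 12, too few to tell. In soleus Ttn, exon 12 stood in 100% of the 84 reads with exon 13 and in 1.61% of the 124 reads without it (Fisher's exact test, adjusted p = 8.04e-56). The Neb pair of exons was exclusive in soleus: 0 of 549 reads with the alternative exon held exon 123, against 99.7% of the 307 reads without it.

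In EDL, several 3' exons of Neb were held in a nested way, but not exon 149. Of 141 reads without exon 151, 0 held exon 148 and 0.709% held exon 150, against 41.1% and 58.9% of the 95 reads with exon 151. Exon 149 stood in 95.7% of the reads without exon 151 and in 84.2% of those with it. All 39 reads with exon 148 held exons 143, 140 and 138, while of the 197 reads without it 23.4% held exon 143.

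Myh6 had 89 full-length reads over its best covered part in EDL and 78 in soleus, against 34450 in cardiac muscle. The values argue against reads of its paralog Myh7 placed on Myh6 as the main source: Myh7 was 453-fold higher in soleus than in EDL, and Myh6 was 0.761-fold (interval 0.554 to 1.04). Cardiac reads carried into the other libraries stay open. The 13 other cardiac-high genes had 27 EDL reads, 0.929% of their 2906 cardiac reads (0.613 to 1.35), against 0.258% for Myh6, but 8 of the 13 had 0 reads in EDL, among them Dsp, with 671 cardiac reads and a limit of 0.447%, which lies above the Myh6 share. Expression of Myh6 in the leg muscles is untested.

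Ratios between libraries were larger by full-length reads than by consensus reads in 98.4% of 61 called values (91.2 to 100) of 39 genes, with a median gain of 1.72 on the log2 scale. A candidate explanation is that clustering merges more reads of abundant transcripts into each consensus read. Genes with at least 30 consensus reads had medians of 4.18, 4.19 and 4.49 full-length reads per consensus read in cardiac muscle, EDL and soleus, against 1.91, 2.08 and 2 for other genes. The percent of larger values was 83.3% at the least in any pair and direction. This does not test for more full-length reads per consensus read in 1 library, since each kind of read had been divided by its own library total, which takes such a difference out beforehand. Which of the 2 folds is nearer to the true ratio is untested.

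In soleus, reads with Neb exon 123 rarely lacked the unannotated 109 nt exon toward the 3' end: 3 of 306 did, 0.980%, against 82 of 550 other reads, 14.9%. Chosen independently, the exons would not give this by Fisher's exact test on full-length reads (p = 1.4e-13). Full-length reads of a cluster are not independent, however. Divided by the mean of 4.80 reads per consensus read, the numbers were 1 of 64 against 17 of 114 (Fisher's exact test, p = 0.0036), and the 88 reads lacking the exon came from 48 consensus reads, so clusters were uneven. The 3 lacking reads with exon 123 came from at most 3 consensus reads. In soleus 67 consensus reads held exon 123, though not all need span both sites, and 48 of 179 lacked the unannotated exon. These values argue against unequal clusters as the only source of the gap in this library. No test on consensus reads was run for this pair of sites, and a link between them has no replicate check.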
